A study of Mus musculus with 6 samples.

How the data were processed

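RNA of MOVAS cells was profiled on 6 single-colour (Cy3) Arraystar mouse circRNA arrays, 3 from cells treated with BaP and 3 from vehicle controls. Per the labels' protocols, total RNA was digested with RNase R to enrich circular RNA and labelled by random priming. Groups and replicate numbers were taken from the sample labels. The labels also name a macrophage line as a reference, and no sample of it was analysed here. Per the file headers, the spot intensities come from Agilent Feature Extraction 11.0.1.1, which subtracted the local background and removed spatial trends to give a processed signal per spot on a linear scale, with 15712 spots per array and no normalization between arrays. Flags for well above background, saturation and outlier spots were made by the same software, per the file headers. The value table deposited by the authors holds log2 values of 14218 circRNA probes, with column medians of 6.09 to 6.10. Its values followed the median spot signal of the same array with rank correlations of 0.999 to 1.00 across probes, and its columns share nearly one distribution, as quantile normalization gives. The submitters' processing notes name limma and Feature Extraction, and the exact steps and any centring behind that table are not given in the sources used here.

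The main values are log2 of the processed signal minus its 75th percentile over the circRNA probes of each array, since over 85% of circRNA probes were well above background on each array. The median signal was 58.2, 55.8 and 35.9 in control replicates 1 to 3 and 56.8, 53.3 and 43.7 in BaP replicates 1 to 3. No spot was saturated, outlier spots were left out, and spots of one probe were averaged. The arrays carry 14236 circRNA probes, 50 mRNA probes, 14 circRNA control probes, 15 negative control probes and 15 custom probes without a gene, and the last 4 kinds have 10 spots per probe. Negative control probes were well above background for 9, 8 and 5 of 15 on control arrays and for 7 of 15 on each BaP array, so this flag alone does not exclude background signal. A probe was tested where it was well above background on at least 3 of the 6 arrays. BaP and control were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment within each kind of probe and a threshold of 0.05. The thresholds of the study, a fold of at least 2.0 and an unadjusted p of at most 0.05, were applied to the same fit. Single values per array were compared with an exact two-sided permutation test, which cannot go below 0.1 for 3 against 3 arrays. Figures were drawn with matplotlib 3.10.9. The circRNA fit was tested on simulated arrays of 13142 probes, 200 of them changed. Each probe had its measured mean and moderated spread, with independent noise of the same size on all arrays. Over 5 runs the fit recovered 55.4% of 2-fold and 91.4% of 4-fold changes, with 10.2 false among 157 calls on average, and the thresholds of the study gave 74.4 false among 224.6 calls. The measured arrays lay at unequal distances from each other, which the simulation left out. Its false calls therefore do not measure those among the real calls.

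The circRNAs ranked in the text are the 10 largest rises and 10 largest falls among those past the adjusted threshold whose groups did not overlap and which were well above background on all arrays of the higher group. Where a circRNA was well above background on no array of 1 group, its bound sets the mean of the brighter group against the mean, per array, of the lowest signal well above background or its own if higher. The files do not pair circRNA probes with host genes, so 2 IDs are printed in each direction, and the planned tests of host gene lists, of circRNAs sharing a host gene and of aryl hydrocarbon receptor hosts were not run. For mRNA probes, 44 of 50 accessions were matched to a symbol in the RefSeq gene table used, without versions, and 6 keep their accession. The mRNA probes that the text does not name enter only its counts. The comparisons of mRNA, circRNA control, negative control and custom probes were added after the data were seen. Spread was estimated from the 48 tested mRNA probes themselves. For the 3 smaller sets it was moderated together with the circRNA probes, a choice made after the fit of the custom probes alone had given all of them one SE. With their own spread, 2 circRNA control, 1 custom and 4 negative control probes passed, against 3, 1 and 2 with the shared spread.

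The alternatives planned before the data were examined were quantile normalization, normexp background correction (offset 50) with quantile normalization, scaling to the median, the percentile over probes detected on all arrays, the value table of the authors, no filter or a stricter filter on dim probes, an intensity trend with robust variance, the replicate number or the slide side as a block, and leaving out each array. The normexp correction used median spot and background intensities, because the files hold no mean spot intensity column. Averaging BaP replicates 1 and 2, a filter at the upper quartile of the negative control probes, fits within 1 slide side and all alternatives for mRNA probes were added after the data were seen. All arrays came from 1 scan. BaP replicates 1 and 2 were kept as separate samples because the labels list them so. The noise between hybridisations of 1 RNA was not measured.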

Results

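MOVAS is a line of mouse aortic smooth muscle cells, and benzo[a]pyrene (BaP) is a polycyclic aromatic hydrocarbon of combustion smoke that binds the aryl hydrocarbon receptor. Circular RNAs (circRNAs) are RNAs whose ends are joined by back-splicing, which leaves them resistant to RNase R, an enzyme that degrades linear RNA. The series asked which circRNAs differ in abundance after BaP exposure. Total RNA of 3 BaP-treated and 3 vehicle-treated samples was digested with RNase R, labelled and hybridised to 6 single-colour arrays carrying 14236 circRNA probes. The BaP dose and the exposure time are not given in the labels used here. Between 12169 circRNA probes (85.5%, BaP replicate 1) and 13373 (93.9%, control replicate 1) were well above background on an array. The median circRNA signal ranged from 35.9 in control replicate 3 to 58.2 in control replicate 1. The labels call the samples of a group biological replicates without saying whether they were separate cultures, so p-values measure the spread between these samples, which may be technical. With 3 arrays per group, the number of arrays limits the precision.

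With the 6 arrays taken as separate samples and no block, 454 of 13151 circRNAs tested differed between BaP and control arrays, of which 319 were higher and 135 lower after BaP (limma, Benjamini-Hochberg adjusted p of 0.05). The count was 0 with the slide side or the replicate number as a block, within 1 slide side, with BaP replicates 1 and 2 averaged to 1 sample, and on leaving out any of 4 of the 6 arrays. Among those that passed, the largest rise was that of ASCRP4006334, at 3.56 ± 0.81 (SD, n = 3) in BaP and -0.06 ± 0.87 (SD, n = 3) in control arrays on a log2 scale relative to each array's 75th percentile. This is a log2 fold change of 3.62 (SE 0.56), or 12.3-fold, with an adjusted p of 0.0300 in limma. ASCRP4011119 rose by 2.77 on the same scale (SE 0.33, adjusted p = 0.0243, limma), from 0.31 ± 0.64 to 3.08 ± 0.28 (SD, n = 3 each). The largest fall among them by the main values was that of ASCRP4013981, from -0.66 ± 0.68 to -3.88 ± 0.46 (SD, n = 3 each), a log2 fold change of -3.22 (SE 0.39, adjusted p = 0.0243, limma). ASCRP4009202 fell from -1.70 ± 0.64 to -4.88 ± 0.41 (SD, n = 3 each), a log2 fold change of -3.18 (SE 0.36, adjusted p = 0.0239, limma), with 2 of the 3 BaP arrays well above background. The size of both falls moved with the processing, for a cause that was not tested, since ASCRP4013981 was at -1.18 with normexp and quantile normalization and at -1.77 in the value table of the authors, and ASCRP4009202 at -0.75 and -1.24. Their BaP levels lie in the range of the negative control probes, whose mean in BaP arrays was -4.30, so the sizes of these falls and their rank are uncertain. For each of these 4 circRNAs the 3 BaP arrays lay on one side of the 3 control arrays. Their calls were kept in 11 of 19 alternatives for ASCRP4006334, ASCRP4011119 and ASCRP4013981 and in 10 of 18 for ASCRP4009202, with adjusted p in limma of up to 0.256, 0.256, 0.253 and 0.245. The files do not pair circRNA probes with host genes, so the circRNAs are given by probe ID and were not grouped by gene.

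**Figure D1:**
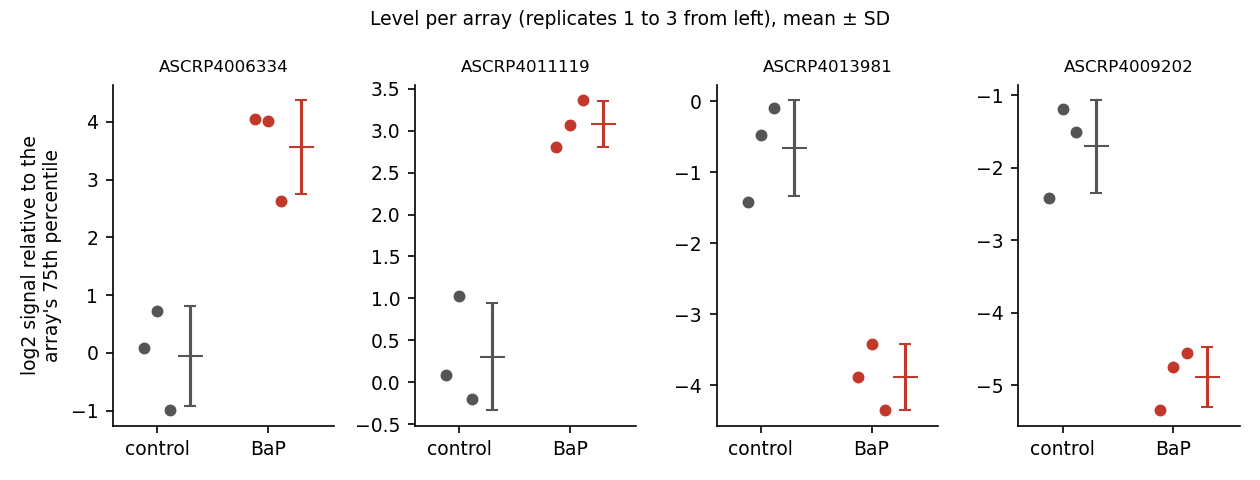
Level of the 2 circRNAs with the largest rises and the 2 with the largest falls among those past the adjusted threshold by the main values, as log2 signal relative to each array's 75th percentile on the vertical axis. Points are the 3 control and 3 BaP arrays, and bars give the mean ± SD. BaP replicate 3 lay at 2.62 for ASCRP4006334, below 4.05 and 4.01 in BaP replicates 1 and 2.

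Of the circRNAs that passed, the 10 with the largest rises had log2 fold changes of 2.26 to 3.62, which were 0.49 to 3.08 with normexp and quantile normalization and 0.87 to 3.34 in the value table of the authors. Of the 10 with the largest falls, 9 had -3.22 to -2.59, which became -2.55 to -0.75 and -2.75 to -1.24, with the largest fall in another circRNA than the 2 named. The other 1 was well above background on no BaP array and by the main values was at least 2.1-fold lower there (adjusted p = 0.0352, limma). Its log2 fold change was -0.23 with normexp and quantile normalization and -0.45 in the value table of the authors, so its size and rank are not known. In 2 of the rises the circRNA was well above background on only 1 or 2 control arrays. In 2 of the falls it was so on only 2 BaP arrays. The median log2 fold change was 1.24 among the circRNAs that rose and -1.22 among those that fell, or -1.17 with 3 circRNAs that were well above background on no BaP array at their bound. At least a 2-fold change was seen in 305 of the 454, with 224 higher and 81 lower, or 80 lower with these bounds. In 4415 circRNAs the arrays of the groups did not overlap, with 1847 higher and 2568 lower in BaP. This is 33.6% of those tested, against 10% on average over all splits of the arrays. Probes that vary together can exceed that average in a split without an effect of BaP, and the shares of the other splits are not given here. More of the circRNAs without overlap were lower with quantile normalization (2054 higher and 2505 lower), with normexp before it (1959 and 2405) and with the 75th percentile over detected circRNAs (1672 and 2996), but more were higher with median scaling (2115 and 1584), so the direction depends on the scaling. The median log2 fold change of all circRNAs tested was -0.09 in the main values and -0.01 with median scaling.

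**Figure D2:**
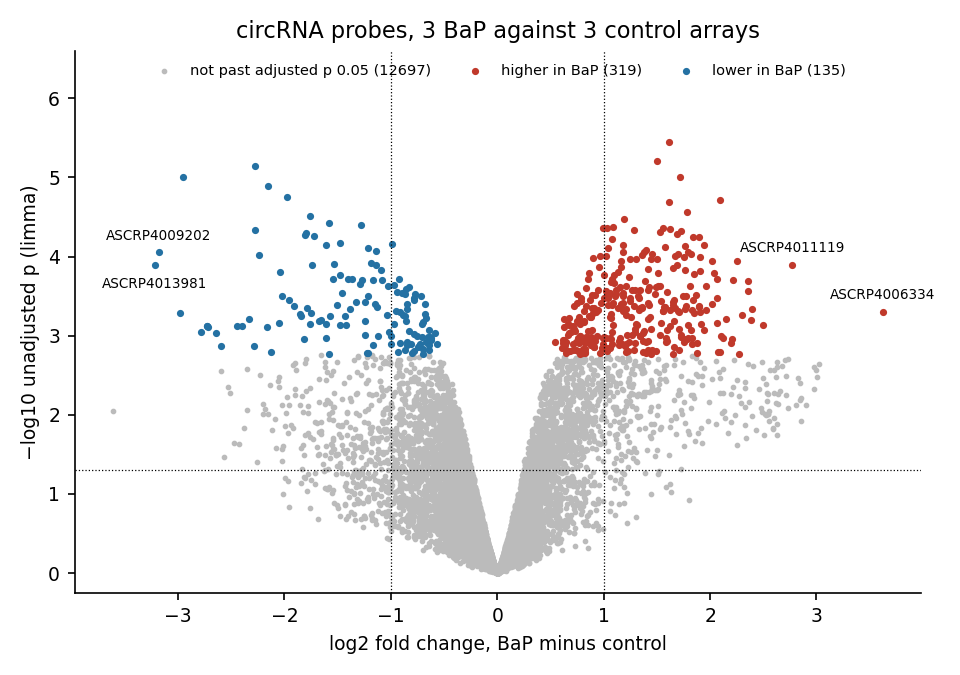
Log2 fold change of the 13151 circRNAs tested (BaP minus control, horizontal axis) against -log10 of the unadjusted limma p (vertical axis). Red points are the 319 circRNAs higher and blue points the 135 lower at an adjusted p of 0.05, and dotted lines mark a 2-fold change and an unadjusted p of 0.05.

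BaP replicate 3 differed from the other BaP arrays. Over 3532 bright circRNA probes the SD between arrays was 0.098 (log2) for BaP replicates 1 and 2, 0.420 and 0.384 for BaP replicate 3 against each of them, and 0.241 to 0.256 between controls. Control replicate 2 lay at 0.318 and 0.313 from BaP replicates 1 and 2, closer to each of them than BaP replicate 3 did. Among circRNAs past the thresholds of the study in BaP replicates 1 and 2 against 2 controls, BaP replicate 3 differed from the control left out in the same direction for 87.6%, 82.7% and 79.7%, with control replicate 1, 2 or 3 left out, against 46.9%, 47.6% and 47.6% for unrelated directions. The median size along that direction was 1.49, 0.80 and 1.26 in BaP replicate 3, against 1.41, 1.46 and 1.39 in BaP replicates 1 and 2, by which these circRNAs were selected. The count of 454 was 1252 without BaP replicate 3 (925 higher and 327 lower), 290 without control replicate 2 (255 higher and 35 lower), and 0 without control replicate 1, control replicate 3, BaP replicate 1 or BaP replicate 2. In those 4 limma fits 2337, 2634, 2668 and 2457 circRNAs had an unadjusted p under 0.05, and all 454 circRNAs kept their direction with such a p. Those 454 were selected on these same arrays, so this is not an independent test of them.

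The controls and BaP replicate 1 lay on one side of the slide, and BaP replicates 2 and 3 on the other, which held no control. With the slide side as a block limma called 0 circRNAs at an adjusted p of 0.05 and 1440 at an unadjusted p of 0.05. Within the first side, 1 BaP array against 3 controls gave 0 and 2110, where the lone BaP array is assumed to vary like the controls. The log2 fold change within that side was 4.11 for ASCRP4006334, 2.50 for ASCRP4011119, -3.21 for ASCRP4013981 and -3.64 for ASCRP4009202, with adjusted p in limma of 0.132, 0.150, 0.132 and 0.130.

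The design text of the series selects circRNAs by a fold change of at least 2.0 and a p of at most 0.05, and names neither a test nor an adjustment. With limma's unadjusted p, 855 circRNAs met both, of which 516 were higher and 339 lower in BaP. Of these, 17 were well above background on no array of 1 group, and with these at their bound 840 met both, 515 higher and 325 lower. All 305 circRNAs that passed the adjusted test with at least a 2-fold change are among them. With normexp background correction and quantile normalization 223 were higher and 69 lower, and in the value table of the authors 326 were higher and 130 lower. The excess of rises was not kept without BaP replicate 2 (476 higher and 505 lower), and was small with BaP replicates 1 and 2 averaged (488 and 466). With the slide side as a block the count was 669, with 483 higher and 186 lower, and within the first side it was 838, with 586 higher and 252 lower.

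**Figure D3:**
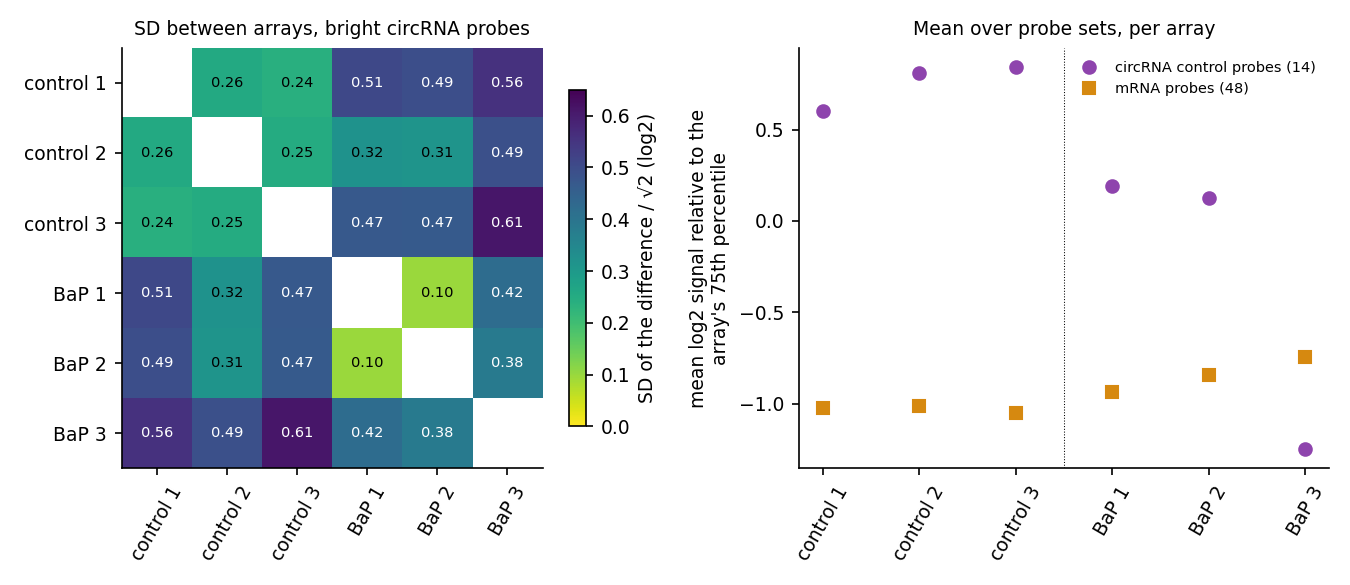
Left, SD of the difference between each pair of arrays divided by the square root of the number of arrays in a pair, over 3532 bright circRNA probes (log2). Right, mean log2 signal relative to the 75th percentile of each array for 14 circRNA control probes (circles) and 48 mRNA probes (squares). BaP replicates 1 and 2 are the closest pair, and the circRNA control probes are lowest in BaP replicate 3.

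The array also carries 50 mRNA probes, read after RNase R digestion. Whether their signal comes from linear RNA that remained or from other RNA that binds the probe was not tested, so a value is that of the probe and not of the gene's mRNA. Of 48 tested, 7 passed an adjusted p of 0.05 in limma, 6 higher and 1 lower in BaP. The probe of Olfr1307, an olfactory receptor gene, rose by 1.33 on the log2 scale (SE 0.19, adjusted p = 0.00718, limma), from 0.56 ± 0.32 to 1.89 ± 0.22 (SD, n = 3 each). Those of Lhx1, a LIM homeobox transcription factor, Tm9sf1, a transmembrane 9 superfamily protein, and Mzb1, an endoplasmic reticulum protein of B cells, rose by 0.92 (SE 0.23), 0.81 (SE 0.18) and 0.73 (SE 0.17), with adjusted p in limma of 0.0424, 0.0390 and 0.0408. The probe of Rab5a, a small GTPase of early endosomes, rose by 0.38 (SE 0.10, adjusted p = 0.0424, limma), a call kept in 2 of 17 alternatives and in none that left out an array, with 0.12 under normexp and quantile normalization. The probe of Taf1a, a subunit of the RNA polymerase I selectivity factor, had a log2 fold change of -0.43 (SE 0.09, adjusted p = 0.0390, limma). The remaining probe, BC057074, was not matched to a gene and rose by 0.87 (SE 0.13, adjusted p = 0.00718, limma). For each of these 7 probes the 3 BaP arrays lay on one side of the 3 controls. These probes were chosen after their values were seen.

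Of 22 gene lists fixed before the data were examined, 5 had a member among the mRNA probes. The autophagy, lysosome and endosome list held Rab5a and Atg3, a conjugating enzyme of autophagy, at 0.32 (SE 0.10, adjusted p = 0.0732, limma). Of these 2 members 1 passed over all mRNA probes and 2 did when adjusted over the list alone. Both fell below the filter set by the negative control probes, and Atg3 was at 0.12 with normexp and quantile normalization. The lipid list held Ppara, a nuclear receptor for fatty acids, at -0.58 (SE 0.19, adjusted p = 0.0732, limma) and Cpt1a, which carries fatty acids into mitochondria, at 0.08 (SE 0.10, adjusted p = 0.613, limma). None of its members passed over all mRNA probes and 1, Ppara, did when adjusted over the list alone. Ppara was well above background on 2 of 3 BaP arrays, lay below the filter set by the negative control probes, and was at -0.08 with normexp and quantile normalization. The xenobiotic list held Gsta4, a glutathione transferase, at 0.09 (SE 0.14, adjusted p = 0.652, limma), which also lay below the filter set by the negative control probes. Prdx2, a peroxiredoxin of the oxidative stress list, was at 0.09 (SE 0.11, adjusted p = 0.564, limma), and Gpi1, a glycolytic enzyme of the energy metabolism list, at 0.18 (SE 0.13, adjusted p = 0.382, limma). For these 3 lists 0 members passed, over all mRNA probes and when adjusted over the list alone, with unadjusted p over 0.05 for each. Gsta4 was at -0.03 without control replicate 1, and Prdx2 at -0.02 within the first slide side. The other 17 lists had no member among the mRNA probes.

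**Figure D4:**
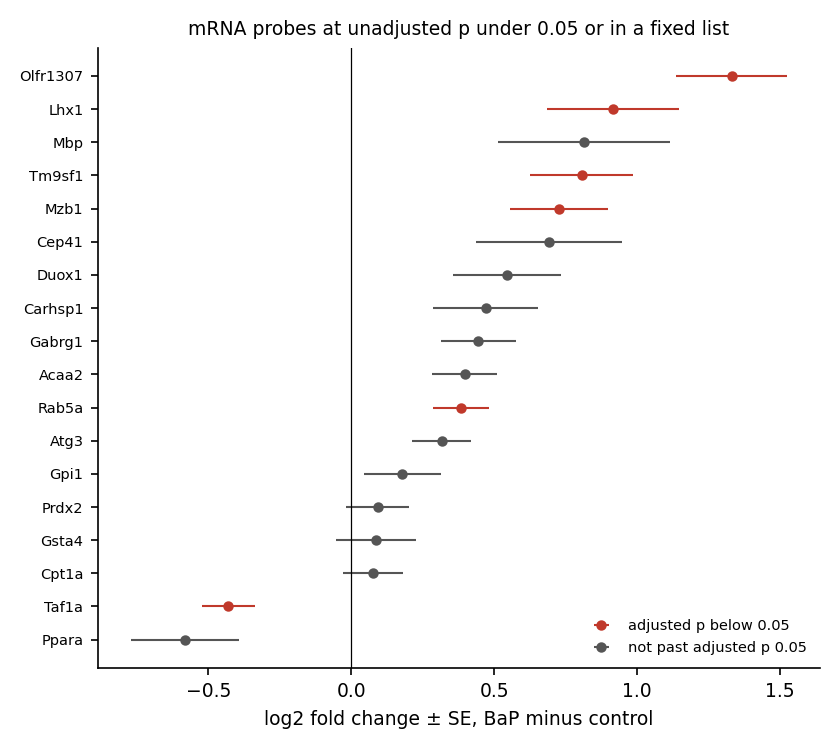
Log2 fold change (BaP minus control) with its SE for the 18 mRNA probes matched to a gene that had an unadjusted p under 0.05 or belonged to a fixed list, in order of size. Red points passed an adjusted p of 0.05 in limma. Olfr1307 lay highest at 1.33, and Ppara lowest at -0.58.

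With the spread moderated together with the circRNA probes 2 of the mRNA probes passed, Olfr1307 and BC057074, each with an adjusted p of 0.0136 in limma, so the calls of the other probes rest on the choice of spread. BC057074 went from -2.55 to -1.68, and negative control probe 16, which should read background, rose by 0.88 from a similar level. With normexp and quantile normalization the log2 fold change was 0.39 for BC057074, 0.33 for Mzb1 and 0.57 for Tm9sf1, and of 18 alternatives 15 kept the call for Olfr1307 and BC057074, 9 for Lhx1, Tm9sf1 and Taf1a and 7 for Mzb1. Without control replicate 1, control replicate 2 or BaP replicate 2 the count of 7 was 2, without control replicate 3 it was 3, and with the slide side as a block or within the first side it was 0, with 7 and 8 probes at an unadjusted p under 0.05 in limma.

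The 14 circRNA control probes of the array had a mean of 0.75 ± 0.13 (SD, n = 3) in control and -0.31 ± 0.81 (SD, n = 3) in BaP arrays. The difference of -1.06 had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow. Means of 0.19 and 0.13 were found in BaP replicates 1 and 2, and of -1.25 in BaP replicate 3, which was the lowest of all arrays for 12 of the 14 probes. Without BaP replicate 3 the difference was -0.59, and within the first slide side it was -0.56. The mRNA probes had a mean of -1.03 ± 0.02 (SD, n = 3) in control and -0.84 ± 0.10 (SD, n = 3) in BaP arrays. This difference of 0.19 also had an exact permutation p of 0.1, and it was 0.14 without BaP replicate 3 and 0.09 within the first slide side. Under the other scalings the difference ranged from -1.09 to -0.72 for the circRNA control probes and from 0.11 to 0.26 for the mRNA probes.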

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

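All tests in this part were chosen after the data were seen. Custom probe 11, which has no gene in the files, stood out because it differed between groups in data that the comparisons above do not use. It was at 4.60 ± 0.53 in BaP and 2.97 ± 0.32 in control arrays (SD, n = 3 each), a log2 fold change of 1.64 (SE 0.30) with an adjusted p of 0.0199 over the 15 custom probes in limma. It was higher in 3 of 3 BaP arrays. Estimated from the custom probes alone, its adjusted p was 1.46e-12 in limma, a value that rests on 1 SE of 0.17 shared by all 15 probes.

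Negative control probes 16 and 7, which should read background, also differed between groups. Of the 7 negative control probes tested, these 2 passed with the spread moderated together with the circRNA probes, and 4 passed with their own spread. Probe 16 was at -1.64 ± 0.12 in BaP and -2.51 ± 0.20 in control arrays (SD, n = 3 each), a log2 fold change of 0.88 with an adjusted p of 0.00521 in limma over the 7 probes tested. Probe 7 was at -3.84 ± 0.11 and -3.44 ± 0.06 (SD, n = 3 each), a log2 fold change of -0.40 with an adjusted p of 0.0403 in limma. No explanation was tested for these 3 probes.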

How the results depend on the processing

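The averaging of BaP replicates, the fits within 1 slide side and all alternatives for mRNA probes were chosen after the data were seen. The 454 circRNAs past an adjusted p of 0.05 became 790 with quantile normalization, 1056 with normexp and quantile normalization, 732 with median scaling and 1097 in the value table of the authors, and the cause was not tested. The count was 0 in limma with the replicate block (2281 at an unadjusted p under 0.05), with the slide side as a block (1440), within slide side 1 (2110) and with BaP replicates 1 and 2 averaged to 1 sample (2544), fits that hold fewer samples or residual degrees of freedom. Leaving out single arrays gave 0 to 1252, with 0 without control replicate 1, control replicate 3, BaP replicate 1 or BaP replicate 2 (2337, 2634, 2668 and 2457 unadjusted), 290 without control replicate 2 and 1252 without BaP replicate 3. The other filters, percentile and variance model gave 320 to 681, and an added 2-fold threshold 305. All 454 circRNAs kept their direction wherever they were tested, 405 of them under the filter for all 6 arrays and 411 under that for negative controls. That was largely fixed by their selection on these same arrays. The 855 circRNAs past the thresholds of the study became 292 with normexp and quantile normalization. With quantile normalization alone they were 874, so the drop came with the normexp step, whose parts were not tested apart. In the value table they were 456, the cause not tested, and the count stayed within 1.5 times elsewhere (669 to 981). Of the 855, 60.4% were higher, against 76.4% with normexp, 71.5% in the value table, 72.2% with the side as a block, 74.9% without BaP replicate 3 and 48.5% without BaP replicate 2. The 7 mRNA probes became 2 with the spread moderated together with the circRNA probes, 2 with median scaling and 3 with no filter on dim probes, the cause not tested. The count was 0 in limma with the replicate block (12 unadjusted), the slide side as a block (7) and within slide side 1 (8), and 2 to 7 on leaving out single arrays. Prdx2 reversed to -0.018 with the slide side as a block and within slide side 1, and Gsta4 ranged from -0.034 to 0.21 on leaving out single arrays, negative without control replicate 1, and neither passed the test in the main comparison. With each probe's group mean taken off, same-numbered arrays of the groups had r of -0.40, 0.13 and -0.26 across probes, which differ in sign. Differently numbered arrays had r of -0.28 to 0.40 on the same measure. These values show no pairing by replicate number, but they were not tested and cannot exclude it. Tests of host gene lists and of circRNAs sharing a host gene were not run. The value table holds no mRNA probes. Dim circRNAs were measured less precisely, with a median SE of 0.21 in the dimmest 4384 against 0.15 in the brightest 4384, and the cause was not tested.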

Other observations

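The tests of chance splits of the mRNA probes and of quantile normalization were written before their results were seen, and the other tests of this part were chosen after. Calls were counted by brightness, without a test of the difference and with a larger median SE in dim probes (0.21) than in bright ones (0.15). Among the 4384 brightest, 189 passed the adjusted threshold in limma, 159 higher and 30 lower in BaP, and among the 4384 dimmest 108 passed, 51 higher and 57 lower. In 25 circRNAs the signal was well above background on all control arrays and on no BaP array, and 2 showed the opposite, 27 in all, while another split of the arrays gave 165.

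The probe of H2-Q7, an MHC class I gene with close relatives that it may also read, was at 3.00, 2.97 and 0.10 in BaP replicates 1 to 3 and at 0.06, 0.50 and 2.25 in control replicates 1 to 3, and the sharing was not examined. Its log2 fold change was 1.08 (SE 0.91, adjusted p = 0.402, limma), and that of Actb, a cytoskeletal actin, was -0.14 (SE 0.25, adjusted p = 0.652, limma). Acaa2, a thiolase of fatty acid oxidation, was at 0.40 (SE 0.11, adjusted p = 0.0643, limma), and Duox1, an oxidase that makes hydrogen peroxide, at 0.54 (SE 0.19, adjusted p = 0.0857, limma), neither past the threshold. For Gsta4 and Prdx2 the sign may depend on the arrays used, with -0.034 for Gsta4 without control replicate 1.

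BaP replicate 3 lay apart from BaP replicates 1 and 2 over circRNA probes and circRNA control probes. Against an intensity-dependent array response, its SD against BaP replicate 2 stayed at 0.356 after quantile normalization, where BaP replicates 1 and 2 differed by 0.098. Against the slide side, BaP replicates 2 and 3 lay on the same side and differed by 0.384, while BaP replicates 1 and 2 lay on different sides. Less circular relative to linear RNA stays open for the array as a whole. Its mRNA probes had a median shift of 0.155 against BaP replicates 1 and 2. Each control array shifted by -0.043 to 0.024 against the other controls. BaP replicate 1 shifted by -0.134, but against a pair that holds BaP replicate 3, so this is no separate measure of the usual shift. Bright circRNA probes rose against mRNA probes by 0.042 (SE 0.10, with the mRNA probes taken as independent). This is opposite in direction to such a loss but within its SE. That same value is far from the fall of -1.63 in the circRNA control probes of BaP replicate 3. It argues against this loss as the cause of their fall only if the mRNA probes read linear RNA, which was not tested. Differences between cultures were not tested.

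The circRNAs that differed between BaP and control arrays numbered 454, and 1 of the 10 splits of the 6 arrays, the real one, gave as many, with 0 as the highest of the others, while 855 passed the thresholds of the study against 191 and 7 mRNA probes passed against 1, and 10 splits allow no share under 0.05. Against the slide side as the whole cause, BaP replicate 1 differed from the closest control on its own side by an SD of 0.318, and from BaP replicate 2 on the other side by 0.098. More residual linear RNA on BaP arrays stays open, because 62.5% of mRNA probes (30 of 48, Wilson 95% interval 48.4% to 74.8%) lay higher in BaP, which neither reaches the 80% set for it nor lies below the 60% set against it. A bound of 65%, under which this value would have counted against it, was used at first although 60% had been noted earlier, and the interval spans both. The interval takes the mRNA probes as independent, although they share the same 6 arrays, and may be too narrow. Whether these probes read linear RNA was not tested, and an effect of BaP stays open beside it.

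BaP replicates 1 and 2 were the closest pair, with an SD of 0.098 against 0.241 for the next. Whether 1 RNA sample was hybridised to 2 arrays cannot be told apart from similar cultures, because the noise between hybridisations was not measured, and spots of one probe within an array differed by an SD of 0.038. With these arrays averaged to 1 sample, limma called 0 circRNAs at an adjusted p of 0.05, 2544 at an unadjusted p of 0.05 and 954 past the thresholds of the study.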
